A study of Mus musculus with 12 samples.

How the data were processed

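The study measured ribosome-bound RNA of enteric glia in 12 C57BL/6 mice. A tamoxifen-dependent Cre recombinase under Sox10 switched on a tagged Rpl22; chow with tamoxifen (400 mg/kg) was fed for 2 weeks and plain chow for 1 week after that. GR159897 at 0.5 mg/kg or 0.1% DMSO was injected daily over 3 days, starting 24 hours before an enema of 0.1 ml that held saline or 5 mg of DNBS in 50% ethanol. Myenteric plexus of the distal colon was collected 48 hours after the enema. Complementary DNA was made from 1 ng of RNA with the SMART-seq v4 kit, and paired-end Nextera libraries were sequenced on an Illumina instrument. The labels name no batch, date or litter.

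The deposited table holds FPKM values (fragments per kilobase of transcript, normalised to all mapped fragments), which the authors gave per assembled locus and library with 2 decimals. The submitters' processing notes name cutadapt 1.10, FastQC 0.10.1, HISAT2 2.0 and StringTie 1.3, with no role or order. The genome build is not given in the sources used here. The values do not tell strands apart. Sums of FPKM differed between libraries, the depth per library is unknown, and no counting interval is given.

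Of 99547 loci, 24432 held an annotated Ensembl transcript and 75115 did not (51585 with a name and 23530 without). The first were analysed, 1 locus per gene symbol with the highest mean, which left out 38 duplicates and gave 24394 symbols; 902 loci merge more than 1 gene and keep all their symbols. This rule was fixed on the structure of the table before any test. Gfap had blank values in all 3 Saline_Vehicle libraries, so it was left out of the comparisons that use that group and nothing was filled in. Positions were taken from GENCODE (GRCm38) through the transcript identifiers, with 23496 symbols matched to a single gene. Of 138 named genes 134 were matched to a single gene, and 42 of these share exon sequence with another gene, 3 on the same strand and 40 on the opposite strand. In all 12 libraries the sex-linked genes matched the sex in the labels, 7 males and 5 females. No pair of libraries was identical and all columns of values were mapped to a sample.

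Values were analysed as log2(FPKM + 1) without rescaling, for genes with at least 1 FPKM in at least 3 libraries (12778 genes). One linear model with a coefficient per group, no sex term and no block was fitted over all 12 libraries (8 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, with a trended and robust prior. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and the threshold was 0.05. The comparisons were DNBS_Vehicle against Saline_Vehicle, Saline_GR159897 against Saline_Vehicle, DNBS_GR159897 against DNBS_Vehicle, DNBS_GR159897 against Saline_GR159897, and the interaction. The average of the DNBS change over both drug arms was added after the data were seen. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

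The procedure was tested on simulated data, in which log2 changes were added to 200 genes in each of 5 runs of the first comparison. It recovered 0.4% of changes of 1, 42% of changes of 2, 72% of changes of 3 and 87.6% of changes of 4, with 6.2 false calls per run on average. The simulated noise was normal, independent between genes and of equal spread in all libraries, and the changed genes had a mean log2 value above 1. The real libraries differ in spread, so these shares and false calls may not hold for them. In the simulated setting most changes of 1 on the log2 scale were missed with 3 libraries per group.

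Gene lists of pathways and cell types were fixed before the data were examined and tested with fry, whose directional p asks whether the members move, on balance, in a single direction, and with camera, which compares a list with the other genes. The p of fry was adjusted over 28 lists within a comparison. With camera and a preset correlation of 0.01, 11, 0, 6, 12, 6 and 12 lists passed in the order of the comparisons above. With an estimated correlation 2, 0, 0, 0, 0 and 3 did. These were matrix remodelling and cytokines in the first comparison, and those and macrophage markers in the averaged contrast. The lists covered enteric glia, reactive glia, myelin, neurotrophic factors, the tachykinin system, purinergic and connexin signalling, cytokines and chemokines, type I interferon, antigen presentation, NF-kB targets, complement, oxidative stress, apoptosis and p53 targets, matrix remodelling, the unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, the cell cycle and immediate early genes. Others held markers of neurons, smooth muscle, interstitial cells of Cajal, fibroblasts, macrophages, neutrophils, epithelium, endothelium and mesothelium. Lists with fewer than 3 measured members were not tested: lymphocyte and mast cell markers had 0 members past the filter, and mitochondrially encoded genes and digestive enzyme genes had 1 each (mt-Nd6 and Cela1).

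Genes were named by a rule fixed before the data were examined. Per comparison these were the 10 higher and 10 lower genes with the largest change among those past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the libraries compared, without predicted genes. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not past the threshold. Up to 4 members of each list that passed, or had a member past the threshold, could be named, and Sox10, S100b, Gfap, Rpl22, Tacr2, Tac1, Tacr1, Tacr3 and Gja1 were named whatever their values. Of the genes the rule gives, 2 are not reported here.

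Alternatives fixed before the data were examined were a pseudocount of 0.1, upper-quartile scaling, quantile normalization, no filter, a filter of 5 FPKM, a block by replicate number, a sex term, library weights, a fit of only the 2 groups compared, and leaving out each library in turn. Added after the data were seen were all loci including those without an annotated transcript, scaling to the annotated total (each library's share of summed FPKM on loci with an annotated transcript), that share as a term, and neutrophil or macrophage markers as a term. The annotated share of DNBS and saline libraries was compared by permuting labels within each drug arm (400 arrangements, two-sided).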

Results

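The 12 libraries hold ribosome-bound RNA from the myenteric plexus of the distal colon of 12 C57BL/6 mice. Enteric glia, the support cells of the gut nervous system, carried a tagged copy of the ribosomal protein Rpl22 after recombination driven by Sox10, and RNA was pulled down through the tag. The mice had an enema of saline or of DNBS, a hapten that causes colitis, given in 50% ethanol. They were injected with DMSO vehicle or with GR159897, an antagonist of the neurokinin-2 receptor (the product of Tacr2). The saline enema is listed without ethanol, so a change with DNBS cannot be told apart from one with ethanol. The 4 groups, Saline_Vehicle, DNBS_Vehicle, Saline_GR159897 and DNBS_GR159897, held 3 libraries each. Sex was not balanced: DNBS_GR159897 held 2 females and 1 male, and each other group 1 female and 2 males. Values are FPKM (fragments normalised to transcript length and to all mapped fragments), so the depth of each library is unknown. Between 10325 and 11157 genes per library reached 1 FPKM. Below, levels are means with their SD over n = 3 libraries. Changes are log2 fold changes of FPKM + 1 with their SE, tested with limma. Tbp, which every cell uses, was listed at 0 in Saline_GR159897 replicate 3, so a listed 0 is not read as absence.

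Glial marker genes were well detected, beside RNA of other cell types. S100b, a calcium-binding protein of glia, lay between 94.0 and 288 FPKM in 11 libraries and at 1.17 FPKM in DNBS_GR159897 replicate 1. Acta2, the actin of smooth muscle, lay between 326 and 1005 FPKM in the same 11 libraries and at 47.4 FPKM in that one. The epithelial genes were high in that library: Epcam, an adhesion protein, was at 183 FPKM against at most 4.86 elsewhere, and Muc2, the mucin of goblet cells, at 350 FPKM against at most 6.94 elsewhere. The share of summed FPKM on assembled loci that hold an annotated transcript was 85.6% ± 7.94 (SD, n = 6) in the saline libraries and 59.5% ± 21.4 (SD, n = 6) in the DNBS libraries, a difference of −26.1 (two-sided permutation test within drug arms, p = 0.01). It was lowest in DNBS_GR159897 replicate 1, at 22.6%. Loci named for Gm42418, Gm26917 or Rn18s, which lie at ribosomal RNA repeats, took 0.48%, 0.86% and 0.18% of summed FPKM in the 3 DNBS_GR159897 libraries and at most 0.05% in each of the other 9.

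**Figure D1:**
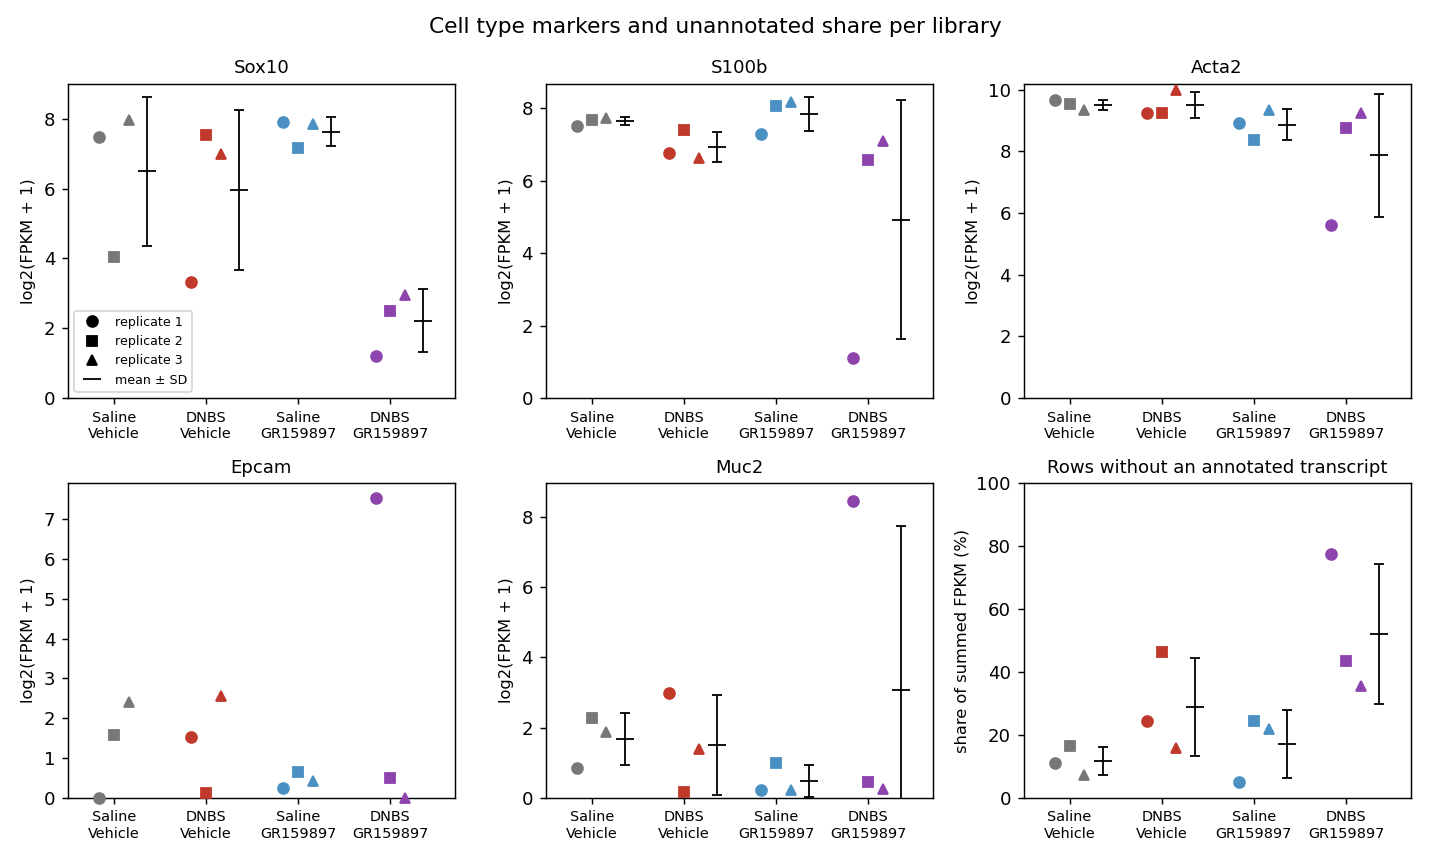
Levels per library of Sox10 and S100b (glia), Acta2 (smooth muscle), Epcam and Muc2 (epithelium) as log2(FPKM + 1), and the percent of summed FPKM on loci without an annotated transcript; points are libraries and bars the mean ± SD of a group, left out for Epcam, which was listed at 0 in some libraries, with lower ends stopped at 0. DNBS_GR159897 replicate 1 has the lowest S100b (1.17 FPKM), the highest Muc2 (350 FPKM) and the highest percent on unannotated loci (77.4%).

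The first comparison asks which transcripts differ 48 hours after DNBS without the antagonist. Timp1, Thbs1, Ankrd1 and Gdf15 were among the genes with more RNA in DNBS_Vehicle than in Saline_Vehicle libraries. Timp1, an inhibitor of matrix metalloproteinases, rose from 13.6 ± 8.96 to 458 ± 91.3 FPKM, a log2 fold change of 5.26 ± 0.92 (adjusted p = 0.0343). Thbs1, the matrix glycoprotein thrombospondin-1, rose from 1.27 ± 0.72 to 31.6 ± 7.22 FPKM, by 3.87 ± 0.60 (adjusted p = 0.0209). Ankrd1, a stress-induced nuclear ankyrin repeat protein, rose by 4.89 ± 0.58 (adjusted p = 0.00917) and Gdf15, a stress cytokine, by 4.84 ± 0.66 (adjusted p = 0.0098). Among the genes that fell were Fat4, an atypical cadherin, from 8.88 ± 1.81 to 0.52 ± 0.31 FPKM, by −2.71 ± 0.36 (adjusted p = 0.0098). Angptl1, an angiopoietin-like secreted protein, fell by −2.83 ± 0.40 (adjusted p = 0.0114). The other genes named by the rule that rose were S100a8 (5.71, a calprotectin subunit of neutrophils), Wfdc17 (4.74), the merged locus of Klk10 and Klk9 (4.12), Tgm1 (3.80, a transglutaminase) and Ptgs2 (3.52, the inducible cyclooxygenase). Their adjusted p ran from 0.0252 for the Klk locus to 0.0497 for S100a8. The others that fell were Tmem140 (−3.00), Sptb (−2.12, a spectrin) and the merged locus of Bglap, Bglap2 and Bglap3 (−2.11). Theirs ran from 0.0366 for the Bglap locus to 0.0428 for Sptb. All 3 DNBS_Vehicle libraries lay beyond all 3 Saline_Vehicle libraries for each of these genes, which the naming rule requires. On the GRCm38 coordinates of the GENCODE annotation, Timp1 (ENSMUSG00000001131) lies on chromosome X at 20870166 to 20874735. Ankrd1 (ENSMUSG00000024803) lies on chromosome 19 at 36111961 to 36120099, and Gdf15 (ENSMUSG00000038508) on chromosome 8 at 70629393 to 70632456. Exons of Thbs1, Tgm1, Fat4, Angptl1, Tmem140 and Sptb overlap those of another gene on the opposite strand, and the values do not tell strands apart. In all, 41 of 12777 genes passed the threshold, 30 higher and 11 lower, against 1612 with an unadjusted p under 0.05. The number that passed was 0 without Saline_Vehicle replicate 1 (1154 with an unadjusted p under 0.05), 14 without replicate 2 and 1 without replicate 3 of that group. It was 17, 20 and 26 without DNBS_Vehicle replicates 1, 2 and 3, so no gene passed in all 6 of these fits. The variance is pooled over all 12 libraries, so libraries outside the comparison count too: 176 genes passed without DNBS_GR159897 replicate 1 (115 higher and 61 lower), and 34 to 47 without each of the other 5 of the antagonist arm.

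Of 28 gene lists, 6 rose and 1 fell in DNBS_Vehicle. All 12 measured matrix remodelling genes had higher values, 5 of them past the threshold over all genes and 11 adjusted over the list alone, with a median log2 fold change of 2.58 (adjusted p = 0.00175). They include Plaur, the urokinase receptor, at 3.28 (adjusted p = 0.0464). Of 17 cytokine and chemokine genes, 14 were higher, with 1 past the threshold over all genes and 8 adjusted over the list alone (median 1.55, adjusted p = 0.0073). Il6 rose by 2.20 (adjusted p = 0.0458). Lif at 3.10, and the chemokines Cxcl1 at 4.0 and Ccl2 at 4.10, had adjusted p of 0.0513, 0.0754 and 0.102. These 2 lists also passed with an estimated correlation (adjusted p = 0.0233 and 0.0299) and in all 12 fits that left out 1 library. The macrophage markers rose, 11 of 11 higher with 1 past the threshold over all genes and 1 adjusted over the list alone (median 0.54, adjusted p = 0.0321, adjusted p = 0.0745 with an estimated correlation). Cd68, a lysosomal protein of macrophages, rose from 1.05 ± 0.71 to 7.02 ± 0.31 FPKM (2.03 ± 0.36, adjusted p = 0.0343).

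Reactive glia genes rose as a list, with 10 of 11 higher, 1 past the threshold over all genes and 6 adjusted over the list alone (median 1.17, adjusted p = 0.0352, adjusted p = 0.0878 with an estimated correlation). Beside Timp1 they include the lipocalin Lcn2 (4.66, adjusted p = 0.0635), the hyaluronan receptor Cd44 (3.54, adjusted p = 0.0882) and the small heat shock protein Hspb1 (5.15, adjusted p = 0.125). Timp1 is also a member of the matrix remodelling list. The libraries hold RNA of other cell types too, so the rise of the reactive glia list cannot be assigned to glia. NF-kB target genes rose, 7 of 8 higher, 0 past the threshold over all genes and 3 adjusted over the list alone (median 0.99, adjusted p = 0.0149, adjusted p = 0.0714 with an estimated correlation). Nfkbiz was at 2.19 (adjusted p = 0.0698). Immediate early genes rose, 10 of 12 higher, 0 over all genes and 3 adjusted over the list alone (median 0.99, adjusted p = 0.0359, adjusted p = 0.0878 with an estimated correlation). Btg2 was at 1.87 (adjusted p = 0.074) and Egr1 at 2.91 (adjusted p = 0.105). Purinergic genes fell, 6 of 8 lower, 0 past the threshold over all genes and 0 adjusted over the list alone (median −0.64, adjusted p = 0.0149, adjusted p = 0.476 with an estimated correlation). Camera with the preset correlation gave an adjusted p of 0.303 for them. Gja1, the connexin of this list, did not pass the filter, so no connexin was among the 8. The ATP receptor subunits P2rx7 and P2rx2 were at −1.23 and −1.36. Beside these lists, 7 of 8 neutrophil markers were higher (median 1.99, adjusted p = 0.0766). The annotated share lay between 53.8% and 84.0% against 83.5% to 92.6% in Saline_Vehicle. The reactive glia and immediate early lists passed in none of the 6 fits that left out 1 library of these 2 groups, with adjusted p of 0.0589 to 0.136 and 0.0589 to 0.151, and the immediate early list was lost without Saline_GR159897 replicate 3 too (0.0531). With a sex term the reactive glia, immediate early and macrophage lists were lost (0.059 each), and with the replicate block they were lost at 0.0588, 0.0899 and 0.0682. Without 1 library of these 2 groups the NF-kB list passed only without DNBS_Vehicle replicate 3 (adjusted p of 0.0527 to 0.0813 without each of the others). In the same 6 fits the macrophage list passed only without DNBS_Vehicle replicate 2 (adjusted p of 0.0574 to 0.136 without each of the others). The purinergic list was lost without Saline_Vehicle replicate 1 (0.0813), Saline_Vehicle replicate 3 (0.0799) and DNBS_Vehicle replicate 2 (0.0691), and when scaled to the annotated total (0.191).

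The other 21 lists did not pass in this comparison. Antigen presentation genes were lower in 11 of 11, 0 past the threshold over all genes and 1 adjusted over the list alone (median −1.98, adjusted p = 0.0892). Enteric glia markers were lower in 11 of 15 (median −0.69, adjusted p = 0.641). The change of Sox10 was −0.54 ± 1.13 (adjusted p = 0.901), and that of S100b −0.71. With the annotated share as a term, S100b was at 0.51. For the other pathways the adjusted p was 0.0892 for apoptosis and p53 targets, 0.094 for oxidative stress, 0.144 for type I interferon, 0.398 for hypoxia and glycolysis, 0.503 for neurotrophic factors and for the cell cycle. It was 0.581 for the unfolded protein response, 0.602 for myelin genes, 0.846 for complement, 0.865 for cholesterol synthesis and 0.961 for the tachykinin system, whose median was 0.51 while the test pointed down. For the markers of other cell types it was 0.581 for interstitial cells of Cajal, 0.846 for mesothelium, 0.865 for smooth muscle and for fibroblasts, 0.938 for epithelium, 0.947 for endothelium and 0.961 for neurons. The fibroblast and endothelial medians, −0.04 and −0.28, were negative while the test pointed up.

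**Figure D2:**
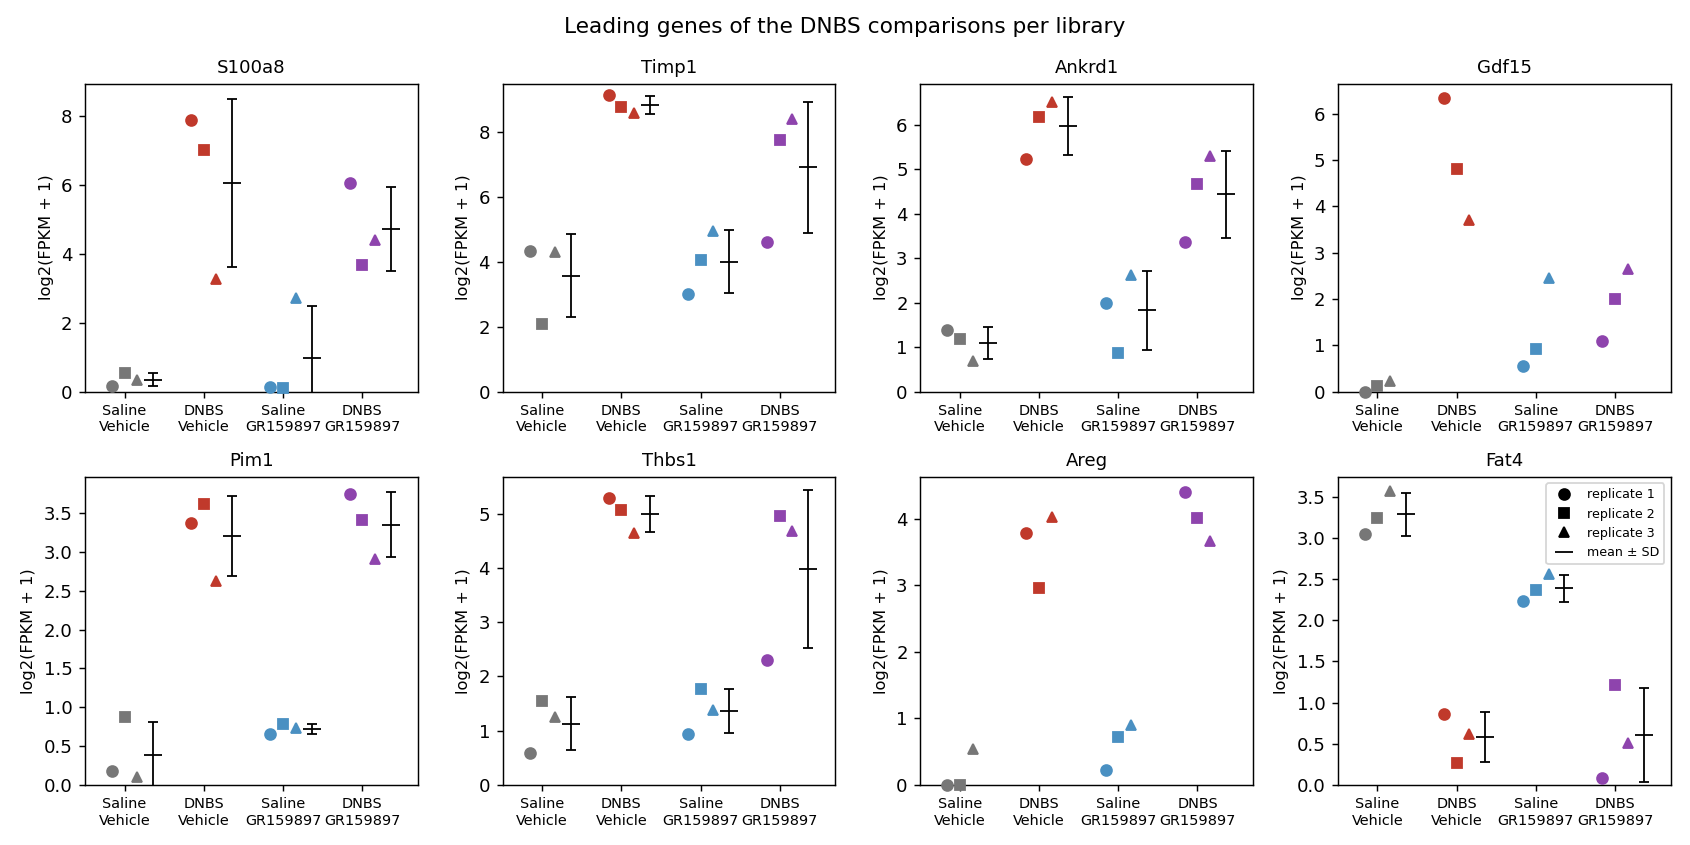
Levels per library of 8 genes named for the DNBS comparisons (S100a8, Timp1, Ankrd1, Gdf15, Pim1, Thbs1, Areg, Fat4) as log2(FPKM + 1) in the 4 groups; points are libraries and bars the mean ± SD of the group, left out for genes listed at 0 in some library. Fat4 is lower, and Ankrd1 and Pim1 are higher, in all 6 DNBS libraries than in all 6 saline libraries; Gdf15 lies between 12.2 and 79.9 FPKM in DNBS_Vehicle and between 1.14 and 5.26 FPKM in DNBS_GR159897.

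The second comparison asks what the antagonist did without inflammation. No gene passed: the count was 0 of 12777 with limma, against 217 with an unadjusted p under 0.05. The genes nearest the threshold, none past it, had lower values with the antagonist. Tmem167b, a Golgi membrane protein, was at 10.6 ± 1.70 FPKM in Saline_Vehicle and at 0.45 ± 0.29 FPKM in Saline_GR159897, a log2 fold change of −3.01 ± 0.40 (adjusted p = 0.0635). Limd1, a LIM domain scaffold protein, was at −2.88 (adjusted p = 0.393), the clock-related gene Ciart at −2.17 (adjusted p = 0.595), the mitochondrial gene mt-Nd6 at −4.79 (adjusted p = 0.772) and Tmem53 at −3.10 (adjusted p = 1). The genes with the smallest p in the other direction, Trmt12 at 2.45, the histone acetyltransferase Kat7 at 1.86, Colgalt1 at 1.80, Ccdc71 at 2.76 and Mtss1l at 1.78, all had an adjusted p of 1. Exons of Tmem167b, Tmem53, mt-Nd6, Colgalt1 and Ccdc71 overlap those of another gene. None of 28 lists passed, with 0 called up and 0 called down by fry and a lowest adjusted p of 0.994. Tacr2, the target of the antagonist, was at 1.33 ± 1.03 and 1.31 ± 1.05 FPKM, a change of −0.04 (adjusted p = 1). The count was 3 without Saline_Vehicle replicate 2, and 1 without each of Saline_GR159897 replicates 1 and 2, DNBS_Vehicle replicate 2 and DNBS_GR159897 replicate 1.

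The third comparison asks what the antagonist did during inflammation. No gene passed between DNBS_GR159897 and DNBS_Vehicle: the count was 0 of 12778 with limma, against 1039 with an unadjusted p under 0.05. None of the genes with the smallest p passed. Cxcl5, a neutrophil-attracting chemokine, was at 6.42, 7.83 and 10.5 FPKM against 0.75, 0.05 and 1.25 FPKM (2.50 ± 0.38, adjusted p = 0.122). Gas1, a cell-surface protein of growth arrest, was at 1.35, 10.9 and 12.7 FPKM (adjusted p = 0.182), and was listed at 0 in the other 9 libraries, so no fold is given. Phlda1 was at 2.97 (adjusted p = 0.38) and the cell cycle phosphatase Cdc25b at 1.86 (adjusted p = 0.54). Ufsp1, at 3.64, 7.42 and 8.08 FPKM, was listed at 0 in all of DNBS_Vehicle (adjusted p = 0.534). In the other direction were Mcts2 at −2.86 (adjusted p = 0.152) and Jaml, an adhesion molecule of leukocytes, at −1.80 (adjusted p = 0.229). Gdf15, the small GTPase Rac1 and the protease Adam10 were at −3.04, −2.92 and −2.92 (adjusted p = 0.406 each). Exons of Gas1, Phlda1, Cdc25b, Jaml and Rac1 overlap those of another gene.

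None of 28 lists passed in this comparison, with 0 called up and 0 called down by fry. The values nearest the threshold were those of immediate early genes, 12 of 12 lower with a median of −0.99 (adjusted p = 0.282), and of hypoxia and glycolysis genes (adjusted p = 0.316). Next, in the order of their p, were oxidative stress genes (median −0.69), matrix remodelling genes, 11 of 12 lower (median −0.82), apoptosis and p53 targets (median −0.45) and reactive glia genes (median −1.70), with an adjusted p of 0.317 each. Among the glial genes, Sox10 was at −3.73 ± 1.13 (adjusted p = 0.545) and Gfap, the intermediate filament of glia, at −2.90 (adjusted p = 0.618). The epithelial markers of DNBS_GR159897 replicate 1 stood apart as given above. The median log2 fold change of all genes was −0.21, and −0.06 without that library. How much of the negative list medians comes from that library is not given here. The count of genes was 2 without DNBS_Vehicle replicate 2, 1 without DNBS_Vehicle replicate 3, 1 without Saline_GR159897 replicate 1, 1 without DNBS_GR159897 replicate 1 and 6 without DNBS_GR159897 replicate 3. When loci without an annotated transcript were tested too, 79 loci passed.

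The interaction asks whether the change with DNBS differed with the antagonist. No gene passed: the count was 0 of 12777 with limma, against 458 with an unadjusted p under 0.05, and 5 with library weights. The smallest adjusted p was 0.0515, that of Gm15453, a processed pseudogene that the naming rule leaves out as a predicted gene. It was at 21, 2.36 and 30.2 FPKM in DNBS_Vehicle and at 7.64, 6.07 and 7.14 FPKM in Saline_GR159897, and was listed at 0 in the other 6 libraries. Gdf15 had 0, 0.08 and 0.17 FPKM in Saline_Vehicle and 79.9, 26.9 and 12.2 FPKM in DNBS_Vehicle. It had 0.46, 0.90 and 4.44 FPKM in Saline_GR159897 and 1.14, 3.00 and 5.26 FPKM in DNBS_GR159897, an interaction of −4.23 ± 0.93 (adjusted p = 0.875). Jaml was at −2.41 and Kat7 at −2.87 (adjusted p = 0.765 each), Trmt12 at −3.42 (adjusted p = 0.947) and Ccdc71 at −4.50 (adjusted p = 0.957). In the other direction Tmem167b was at 2.69 (adjusted p = 0.765), Limd1 at 3.13 (adjusted p = 0.908), and Tmem53 at 3.95 and Phlda1 at 3.60 (adjusted p = 0.957 each). Cxcl5, listed at 0 in all of Saline_Vehicle, had an adjusted p of 0.957. Sox10 was at −4.87 ± 1.59 and Tacr2 at −0.52 (adjusted p = 0.957 and 0.962). None of 28 lists passed, with 0 called up and 0 called down by fry. The lists with the smallest p were immediate early genes (median −1.16), purinergic genes (median −0.62) and matrix remodelling genes (12 of 12 negative, median −1.18), with an adjusted p of 0.628 each. The median interaction of all genes was −0.18, and −0.03 without DNBS_GR159897 replicate 1. How much of these list medians comes from that library is not given here. The count of genes was 2 without Saline_Vehicle replicate 1 and 2 without Saline_Vehicle replicate 2. It was 1 without DNBS_Vehicle replicate 2, 2 without DNBS_Vehicle replicate 3, 1 without DNBS_GR159897 replicate 1 and 1 without DNBS_GR159897 replicate 3.

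The fourth comparison asks which transcripts differ with DNBS while the antagonist is given. Areg, Ctss and Cxcl5 were among the genes that rose in DNBS_GR159897, and Sox10, Naaa and Ctso among those that fell. Areg encodes amphiregulin, a ligand of the epidermal growth factor receptor. It was at 20.3, 15.2 and 11.7 FPKM against 0.17, 0.65 and 0.87 FPKM in Saline_GR159897, a log2 fold change of 3.42 ± 0.39 (adjusted p = 0.00528). Ctss, the lysosomal protease cathepsin S of antigen-presenting cells, rose from 0.83 ± 0.12 to 17.5 ± 6.40 FPKM (3.28 ± 0.44, adjusted p = 0.0152), and Cxcl5 rose by 2.80 ± 0.38 (adjusted p = 0.0152). Sox10, the transcription factor of glial identity and the driver of the tag, fell from 203 ± 53.7 to 4.24 ± 2.77 FPKM, by −5.41 ± 1.13 (adjusted p = 0.0395). Sox10 was also low beside S100b in 2 libraries of the vehicle arm, at 15.4 FPKM with S100b at 202 FPKM in Saline_Vehicle replicate 2 and at 9.04 with 108 FPKM in DNBS_Vehicle replicate 1, so its low values were not particular to DNBS_GR159897. The values are per assembled locus, and whether the assembly of the Sox10 locus plays a part in the low values was not tested, so the size of this fall is uncertain. Naaa, a lysosomal amidase, was at 103, 45.4 and 49.0 FPKM in Saline_GR159897 and at 1.16, 8.43 and 4.80 FPKM in DNBS_GR159897 (−3.67 ± 0.54, adjusted p = 0.0152). Ctso, another cathepsin, fell by −4.14 ± 0.68 (adjusted p = 0.0251). The others that rose were Myh9 (3.56, a non-muscle myosin), Plaur (3.23), Mir142hg (2.99, a host gene of a blood cell microRNA), Snhg15 (2.98) and Xdh (2.81, xanthine dehydrogenase). Their adjusted p ran from 0.0152 for Snhg15 to 0.0395 for Xdh. Gas1 rose too, listed at 0 in all of Saline_GR159897 (adjusted p = 0.0353). The others that fell were Cxx1a (−5.97), Lpar1 (−4.09, a receptor of lysophosphatidic acid), Serpinh1 (−4.0, a collagen chaperone), Aldoc (−3.78, a brain and glial aldolase), Mest (−3.77), Tspan31 (−3.76) and Morn4 (−3.38). Theirs ran from 0.0316 for Morn4 to 0.0458 for Mest. For each of these genes the libraries of the 2 groups did not overlap, which the naming rule requires. Areg (ENSMUSG00000029378) lies on chromosome 5 at 91139599 to 91148432 and Sox10 (ENSMUSG00000033006) on chromosome 15 at 79154908 to 79165240. Exons of Gas1, Snhg15, Mest and Tspan31 overlap those of another gene.

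In all, 176 of 12778 genes passed between DNBS_GR159897 and Saline_GR159897, 49 higher and 127 lower, against 2900 with an unadjusted p under 0.05. The 2 groups also differ wholly in the share on ribosomal RNA loci given above, and whether this bears on the calls was not tested. The count was 4 without Saline_GR159897 replicate 1, 72 without replicate 2 and 4 without replicate 3 of that group. It was 48 (31 higher, 17 lower) without DNBS_GR159897 replicate 1, which stands apart, and 604 without replicate 3. Of the libraries outside the comparison, it was 21, 50 and 19 without Saline_Vehicle replicates 1, 2 and 3 and 68 without DNBS_Vehicle replicate 1. Areg passed in all 12 fits that left out 1 library, Cxcl5 in 11, Ctss, Naaa and Snhg15 in 10 and Ctso in 9. Serpinh1 passed in 7, Plaur, Gas1, Aldoc and Morn4 in 6, and Myh9, Mir142hg and Lpar1 in 5. Cxx1a and Tspan31 passed in 4, Xdh in 3 and Mest in 2. Sox10 did not pass without Saline_Vehicle replicates 1 and 3, any 1 of the 3 Saline_GR159897 libraries or DNBS_GR159897 replicates 1 and 2 (adjusted p of 0.0544 to 0.163). The balance of directions followed the scaling: 27.8% of the genes that passed were higher, against 54.7% with upper-quartile scaling and 80.8% when scaled to the annotated total. The median log2 fold change of all genes was −0.27, 0.02 and 0.37 in these. With the annotated share as a term, 1 gene passed, and 0 of the 176 calls were kept.

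Of 28 lists, 3 rose and 3 fell in this comparison, none of them with an estimated correlation. Matrix remodelling genes rose, 11 of 12 higher, 2 past the threshold over all genes and 9 adjusted over the list alone (median 1.52, adjusted p = 0.016, adjusted p = 0.111 with an estimated correlation). Cytokine and chemokine genes rose, 14 of 17 higher, 1 over all genes and 3 adjusted over the list alone (median 1.26, adjusted p = 0.0221, adjusted p = 0.111 with an estimated correlation). Il11 was at 1.69 (adjusted p = 0.062) and Cxcl2 at 3.31 (adjusted p = 0.124). Macrophage markers rose, 10 of 11 higher, 0 over all genes and 2 adjusted over the list alone (median 1.00, adjusted p = 0.016, adjusted p = 0.11 with an estimated correlation). The mannose receptor Mrc1 was at 1.53 (adjusted p = 0.06). Purinergic genes fell, 6 of 8 lower, 0 over all genes and 4 adjusted over the list alone (median −1.13, adjusted p = 0.00109, adjusted p = 0.357 with an estimated correlation). Camera with the preset correlation gave an adjusted p of 0.16 for them. P2rx7 was at −2.06 (adjusted p = 0.0519). Type I interferon genes fell, 11 of 11 lower, 1 over all genes and 4 adjusted over the list alone (median −1.29, adjusted p = 0.0221, adjusted p = 0.357 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like antiviral protein, fell by −2.55 ± 0.48 (adjusted p = 0.0369). Oasl2 did not pass without Saline_Vehicle replicates 1, 2 or 3, Saline_GR159897 replicates 1 or 3 or DNBS_GR159897 replicate 1 (adjusted p of 0.0577 to 0.158). Apoptosis and p53 targets fell, 5 of 8 lower, 0 over all genes and 1 adjusted over the list alone (median −0.68, adjusted p = 0.0202, adjusted p = 0.693 with an estimated correlation). The pro-apoptotic gene Bbc3 was at −1.59 (adjusted p = 0.0505). The direction of this list reversed when scaled to the annotated total (adjusted p = 0.831).

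Without DNBS_GR159897 replicate 3 the matrix, macrophage and apoptosis lists were lost (0.0572 each), as was the matrix list without Saline_GR159897 replicate 1 (0.0526). The cytokine list was lost without Saline_GR159897 replicate 1 (0.0805), Saline_GR159897 replicate 2 (0.0653), DNBS_GR159897 replicate 2 (0.061) and DNBS_GR159897 replicate 3 (0.0826). The interferon list was lost without Saline_GR159897 replicate 1 (0.0805), Saline_GR159897 replicate 3 (0.0691), DNBS_GR159897 replicate 1 (0.0939) and DNBS_GR159897 replicate 3 (0.0623). It was also lost with quantile normalization (0.0537), with the replicate block (0.0557), with the annotated share as a term (0.309) and when scaled to the annotated total (0.129). The block also ended the calls of the cytokine and macrophage lists (0.0557 each), and the annotated share that of the cytokine list (0.122). The apoptosis list was lost with upper-quartile scaling (0.316), with quantile normalization (0.417) and with the annotated share (0.136). The purinergic list passed in all 12 fits that left out 1 library and was lost when scaled to the annotated total (0.128). Among lists that did not pass, enteric glia markers were lower in 14 of 16 (median −1.75, adjusted p = 0.13), 1 past the threshold over all genes and 5 adjusted over the list alone. S100b was at −2.92 (adjusted p = 0.165), and Gfap at −2.40 (adjusted p = 0.325) and at 1.11 with the annotated share as a term. The myelin protein Mbp fell by −2.51 ± 0.44 (adjusted p = 0.0316) and Nfkbiz rose by 2.29 ± 0.45 (adjusted p = 0.0374), in lists with adjusted p of 0.473 and 0.0681. Mbp and Nfkbiz were lost without Saline_Vehicle replicates 1 and 3, any 1 of the 3 Saline_GR159897 libraries or DNBS_GR159897 replicate 1, and Nfkbiz also without Saline_Vehicle replicate 2 or DNBS_GR159897 replicate 2 (adjusted p up to 0.158 each). Epithelial markers were higher in 9 of 9 (median 2.42, adjusted p = 0.274) and antigen presentation genes lower in 11 of 11 (median −2.60, adjusted p = 0.0681). Cell cycle genes were higher in 8 of 8 (median 1.42, adjusted p = 0.0876) and smooth muscle markers lower in 10 of 12 (median −0.86, adjusted p = 0.59). DNBS_GR159897 replicate 1 weighs on the epithelial, cell cycle and smooth muscle values. Its mean log2 level was 7.07 for epithelial markers against 1.27 and 1.69 in replicates 2 and 3. For cell cycle genes it was 3.185 against 0.50 and 1.74, and for smooth muscle markers 3.91 against 7.55 and 7.59.

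**Figure D3:**
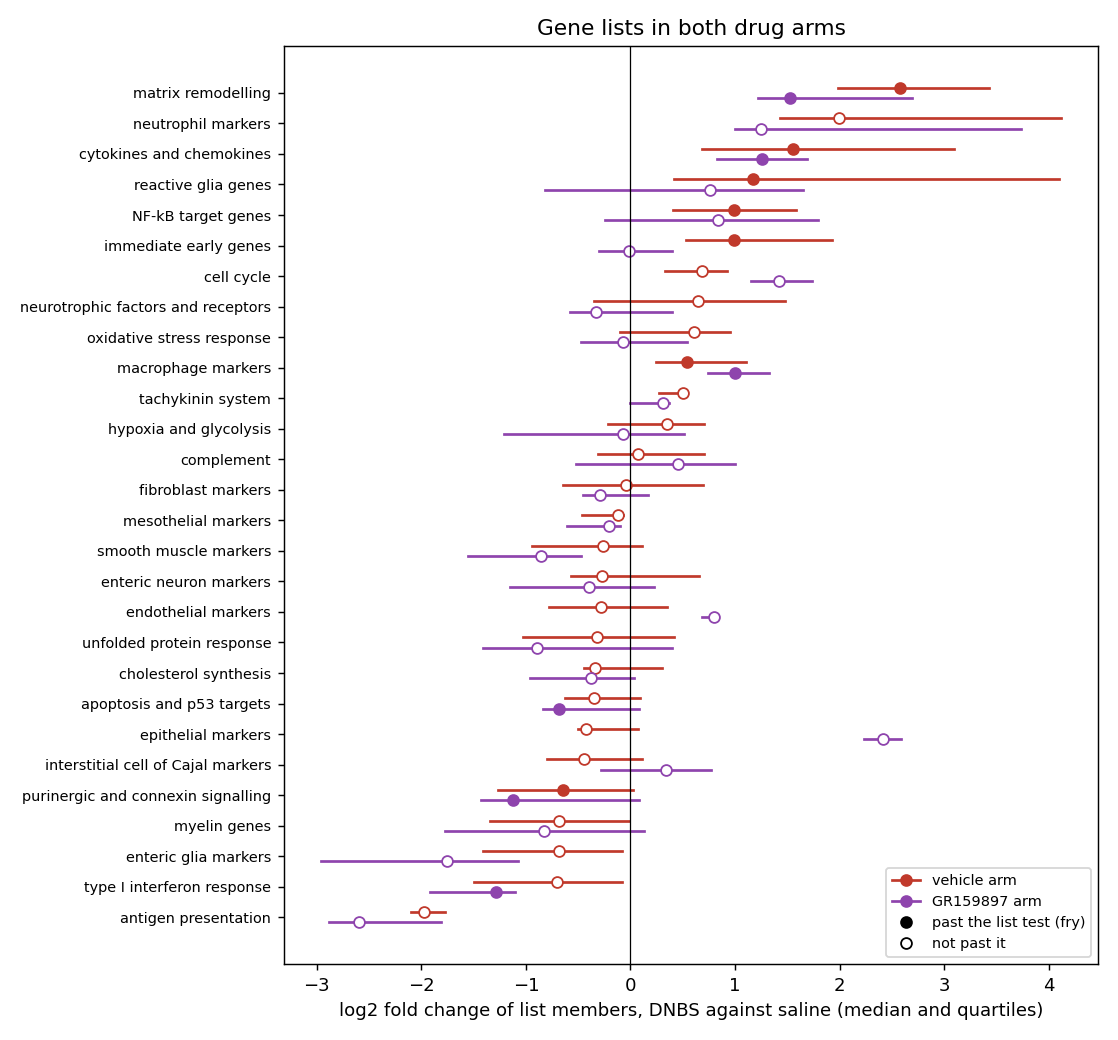
Median (point) and quartiles (line) of the log2 fold changes of the members of 28 gene lists, for DNBS_Vehicle against Saline_Vehicle (red) and DNBS_GR159897 against Saline_GR159897 (purple); filled points passed the directional list test at an adjusted p of 0.05. Matrix remodelling genes have medians of 2.58 and 1.52 in the 2 comparisons, and epithelial markers medians of −0.43 and 2.42, not past the test. The mean log2 level of epithelial markers was 7.07 in DNBS_GR159897 replicate 1 and 1.27 and 1.69 in replicates 2 and 3.

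The 2 DNBS comparisons share no library, though both use the variance pooled over all 12, so their calls are not fully independent. The annotated share was also lower on average with DNBS in each arm, so shared calls cannot tell DNBS apart from the share. Of the 30 genes higher in DNBS_Vehicle and the 49 higher in DNBS_GR159897, 8 were shared, where 0.12 would be with independent lists. They include Areg, Ankrd1, Plaur, Slfn2 and Pim1, a survival kinase. Of the 11 and 127 lower genes, 9 were shared, where 0.11 would be. They include Fat4, Angptl1, Sptb and the cadherin Cdh4. Of the 30 higher calls of the vehicle arm 28 had the same sign in the antagonist arm, with a median log2 fold change of 3.17 in the first and 1.65 in the second. Of the 11 lower calls all 11 did, with −2.71 and −1.997. These genes were chosen for passing in the vehicle arm, which favours a larger change there. Without DNBS_GR159897 replicate 1, 115 genes were higher and 61 lower in the vehicle arm and 31 and 17 in the antagonist arm, with 22 and 9 shared (0.28 and 0.08 with independent lists). The medians of the vehicle calls were then 2.20 and 1.69 in the 2 arms for the higher and −2.04 and −1.69 for the lower. Slfn2 and Cdh4 are named here after their values were seen.

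Averaged over both drug arms, a contrast chosen after the data were seen, the change with DNBS gave many more calls. Areg rose by 3.42 ± 0.27 (adjusted p = 0.000193), Pim1 by 2.73 ± 0.27 (adjusted p = 0.000699) and Ankrd1 by 3.76 ± 0.41 (adjusted p = 0.00158). Plaur and Thbs1 rose by 3.25 ± 0.43 each (adjusted p = 0.00239 each). S100a8 rose by 4.72 ± 0.76 (adjusted p = 0.00588). Tgm1 (3.20), the platelet and macrophage chemokine Pf4 (2.96) and the actin regulator Abi1 (2.75) rose as well. Of the genes that passed and meet the naming rule, which asks for a level of 5 FPKM and no overlap between libraries, those that fell most were Cxx1a (−4.25), the phosphatase Dusp26 (−3.91), Ctso (−3.60), the prion protein locus merged with Prn (−3.44), and Aldoc (−3.07). Next were the extracellular superoxide dismutase Sod3 (−3.04), Tmprss5 (−3.00), Art3 (−3.00), Slc22a17 (−2.98) and Mest (−2.95), with adjusted p from 0.00239 for Ctso to 0.016 for Art3. Exons of Thbs1, Pim1, Tgm1, Abi1, Art3 and Mest overlap those of another gene. In all, 1226 of 12777 genes passed, 353 higher and 873 lower, against 3611 with an unadjusted p under 0.05. Each gene named for the averaged contrast so far passed in all 12 fits that left out 1 library. The count was 463, 667 and 397 without Saline_Vehicle replicates 1, 2 and 3, 666 without DNBS_Vehicle replicate 1, and 436 and 580 without Saline_GR159897 replicates 1 and 3. Without DNBS_GR159897 replicate 1 it was 1214. The share of calls that were higher, 28.8%, was 51.8% with upper-quartile scaling and 70.5% when scaled to the annotated total, with medians of all genes of −0.18, 0.02 and 0.26. With the annotated share as a term 68 genes passed, 58 of them higher.

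Of 28 lists in the averaged contrast, 6 rose and 4 fell. Matrix remodelling genes rose, 11 of 12 higher, 8 past the threshold over all genes and 11 adjusted over the list alone (median 2.11, adjusted p = 0.000312). Cytokines and chemokines rose, 13 of 17 higher, 9 over all genes and 11 up and 1 down adjusted over the list alone (median 1.62, adjusted p = 0.00125). Macrophage markers rose, 10 of 11 higher, 4 over all genes and 4 adjusted over the list alone (median 0.85, adjusted p = 0.00188). Each of these 3 lists had an adjusted p = 0.0311 with an estimated correlation. Timp1 rose by 4.09, the chemokines Ccl7, Cxcl2, Ccl2 and Cxcl1 by 3.74, 3.47, 2.98 and 2.53, and Cd68 by 1.25 (adjusted p from 0.00513 for Timp1 to 0.0252 for Cxcl1). The 4 chemokines were lost without Saline_Vehicle replicate 3 and without Saline_GR159897 replicate 1, all but Cxcl2 without Saline_Vehicle replicate 1, and Cxcl1 without DNBS_Vehicle replicate 1 (adjusted p up to 0.0716). NF-kB targets rose, 6 of 8 higher, 3 over all genes and 5 adjusted over the list alone (adjusted p = 0.0041, adjusted p = 0.0952 with an estimated correlation). Reactive glia genes rose, 8 of 11 higher, 5 over all genes and 6 adjusted over the list alone, with Lcn2 at 3.13 and Cd44 at 2.66 (adjusted p = 0.0159 and 0.0156). Neutrophil markers rose, 7 of 8 higher, 4 over all genes and 7 adjusted over the list alone. Both lists had an adjusted p of 0.0266, and an adjusted p = 0.258 with an estimated correlation. As above, the rise of the reactive glia list cannot be assigned to glia.

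Antigen presentation genes fell in the averaged contrast, 11 of 11 lower, 6 over all genes and 10 adjusted over the list alone (median −2.20, adjusted p = 0.0126). Type I interferon genes fell, 11 of 11 lower, 3 over all genes and 5 adjusted over the list alone (median −1.29, adjusted p = 0.0105). Purinergic genes fell, 6 of 8 lower, 2 over all genes and 4 adjusted over the list alone (median −0.72, adjusted p = 0.000312, adjusted p = 0.137 with camera and the preset correlation). Each of these 3 had an adjusted p = 0.258 with an estimated correlation. Apoptosis and p53 targets fell, 6 of 8 lower, 1 over all genes and 1 adjusted over the list alone (median −0.35, adjusted p = 0.0041, adjusted p = 0.614 with an estimated correlation). Irf7, a regulator of interferon genes, fell by −1.29 (adjusted p = 0.00798), P2rx7 by −1.65 (adjusted p = 0.0139) and the guanylate-binding protein Gbp2 by −3.13 (adjusted p = 0.0209, lost without Saline_GR159897 replicate 1 at 0.055). B2m, the light chain of class I molecules, fell by −2.93 (adjusted p = 0.0388). It passed only without DNBS_Vehicle replicate 3, Saline_GR159897 replicate 2 or DNBS_GR159897 replicates 1 or 3, with adjusted p of 0.0522 to 0.0954 without each of the others. With the annotated share as a term the averaged contrast lost the interferon (0.221), antigen presentation (0.228), apoptosis (0.0657) and neutrophil (0.498) lists. The interferon list was also lost when scaled to the annotated total (0.0738), and the apoptosis list with upper-quartile scaling (0.121), with quantile normalization (0.255) and, reversed, when scaled to the annotated total (0.907). The reactive glia list was lost without Saline_Vehicle replicates 1 (0.0526) and 3 (0.0585), Saline_GR159897 replicates 1 (0.066) and 2 (0.0615) and DNBS_GR159897 replicate 2 (0.0942). The neutrophil list was lost without Saline_Vehicle replicates 1 (0.0614), 2 (0.0538) and 3 (0.0588), DNBS_Vehicle replicate 2 (0.0666) and Saline_GR159897 replicates 1 (0.066) and 2 (0.0615).

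Enteric glia markers did not pass as a list in the averaged contrast, with 12 of 15 lower, 4 past the threshold over all genes and 4 adjusted over the list alone (median −1.49, adjusted p = 0.12). Of them Sox10 fell by −2.98 ± 0.80 (adjusted p = 0.0374, with the same doubt about its locus as above), the endothelin receptor Ednrb by −1.85 (adjusted p = 0.0441), the neuregulin receptor Erbb3 by −1.18 (adjusted p = 0.0388) and Art3 as above. Ednrb passed only without DNBS_Vehicle replicate 2, Saline_GR159897 replicate 2 or DNBS_GR159897 replicate 3, with adjusted p of 0.0655 to 0.108 without each of the others. Erbb3 passed only without DNBS_Vehicle replicate 2 or any 1 of the 3 DNBS_GR159897 libraries, with 0.0551 to 0.0864 without each of the others. Sox10 did not pass without Saline_Vehicle replicates 1 and 3, DNBS_Vehicle replicate 1, Saline_GR159897 replicates 1 and 3 or DNBS_GR159897 replicates 1 and 2 (adjusted p of 0.0525 to 0.0946). S100b at −1.82 (adjusted p = 0.169) did not pass and was at 0.037 with the annotated share as a term. Epithelial markers were higher in 9 of 9 (median 1.15, adjusted p = 0.5), and smooth muscle markers had a median of −0.58 (adjusted p = 0.554). DNBS_GR159897 replicate 1 weighs on both. Its mean log2 level of epithelial markers was 7.07 against 1.27 and 1.69 in replicates 2 and 3, and that of smooth muscle markers 3.91 against 7.55 and 7.59.

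The tachykinin genes bear on the target of the antagonist. Tacr2 stayed low in every group, at 1.33 ± 1.03, 3.07 ± 3.62, 1.31 ± 1.05 and 1.36 ± 1.11 FPKM in Saline_Vehicle, DNBS_Vehicle, Saline_GR159897 and DNBS_GR159897. It passed in no comparison, with 0.52 for DNBS in the vehicle arm (adjusted p = 0.797) and 0.26 averaged (adjusted p = 0.744). Tac1, the gene of substance P and neurokinin A, was at 23.9 ± 5.57, 45.2 ± 32.4, 18.3 ± 6.44 and 36.8 ± 22.8 FPKM (0.66 averaged, adjusted p = 0.422), and Tacr1 at 0.41 averaged (adjusted p = 0.394). Tacr3, the neurokinin-3 receptor of enteric neurons, fell with DNBS in the antagonist arm by −2.18 ± 0.44 (adjusted p = 0.0382) and averaged by −1.98 ± 0.31 (adjusted p = 0.00513). It was at −1.77 ± 0.44 in the vehicle arm (adjusted p = 0.131). Its levels were 4.93, 6.24 and 6.58 FPKM in Saline_Vehicle, 0.18, 2.08 and 1.25 in DNBS_Vehicle, 9.69, 4.33 and 5.01 in Saline_GR159897 and 0, 1.25 and 0.64 in DNBS_GR159897. In the antagonist arm Tacr3 did not pass without any 1 of the 3 Saline_Vehicle or 3 Saline_GR159897 libraries or DNBS_GR159897 replicate 1 (adjusted p of 0.0548 to 0.162), while the averaged change passed in all 12 such fits. Rpl22, the tagged gene, rose averaged by 1.17 ± 0.32 (adjusted p = 0.0417), from 7.81 ± 1.63 to 13.6 ± 0.60 FPKM in the vehicle arm and from 5.81 ± 3.48 to 17.5 ± 3.87 FPKM in the antagonist arm. It passed in 3 of 12 such fits, those without Saline_GR159897 replicates 2 and 3 and DNBS_GR159897 replicate 1. Gja1, the connexin-43 gene, was under 1 FPKM in 10 of 12 libraries, at 9.25 FPKM in DNBS_Vehicle replicate 2 and 1.44 FPKM in DNBS_GR159897 replicate 2, and was not tested. Tacr2 (ENSMUSG00000020081) lies on chromosome 10 at 62252438 to 62265990 and Tacr3 (ENSMUSG00000028172) on chromosome 3 at 134829007 to 134934579.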

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

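The tests of DNBS_GR159897 replicate 1, the tests with the annotated share or immune cell markers as a term, and the tests of the DNBS change averaged over both drug arms were chosen after the results were seen, while the counts over other splits were planned for the other comparisons.

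Signal on loci without an annotated transcript, which the comparisons do not use, was above the highest Saline_Vehicle library (16.5% of summed FPKM) in 7 libraries. It was 24.4% and 46.2% in DNBS_Vehicle replicates 1 and 2, 24.6% and 21.9% in Saline_GR159897 replicates 2 and 3, and 77.4%, 43.6% and 35.5% in DNBS_GR159897 replicates 1, 2 and 3. For 5 of 137 genes checked, all libraries moved in opposite directions with DNBS in the 2 drug arms. The interaction, on the log2 scale, was −3.42 for Trmt12, −2.87 for Kat7, −2.22 for Colgalt1, −4.50 for Ccdc71 and −2.66 for Mtss1l. None passed the adjusted threshold, and all were named because they had the smallest p for Saline_GR159897 against Saline_Vehicle, so their Saline_GR159897 values were chosen for being high. Groups of 3 libraries were not tested for outlying values.

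DNBS_GR159897 replicate 1 stood apart from the other 2 libraries of its group. Its epithelial markers lay higher by a median of 4.894 (log2, 14 of 14 above both, quartiles 4.286 to 5.994), and the abundant members took part, with Muc2 at 350 FPKM, Epcam at 183, Krt19 at 109 and Lgals4 at 106, which is consistent with RNA of epithelial cells. A lower share of glial RNA alone is argued against, since smooth muscle markers lay lower by a median of −3.459 (12 of 12 below both) while epithelial markers lay higher. Dilution by unannotated fragments alone is argued against too, since the glial markers still lay lower, at −2.266 (upper quartile −1.004), after scaling to the annotated total. A difference in the response of this mouse to DNBS remains open and untested, as does a difference in dissection.

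The genes that passed for DNBS averaged over both drug arms numbered 1226, and the annotated share differed between the same groups. With the share as a term the 353 genes called higher kept a median of 0.929 of their log2 change (lower quartile 0.715, median 1.465 before and 1.403 after). The share was lower with DNBS, and dilution by unannotated loci would lower these genes, so the result does not bear on dilution. The slope of the term comes from differences within groups, and thus in part from DNBS_GR159897 replicate 1, which stands apart. Its share was 22.6% against 56.4% and 64.5% in replicates 2 and 3. No fit of the kept change left that library out, so the result does not settle whether other effects that follow the share are the whole cause for them. The 873 called lower kept 0.697 (lower quartile 0.488; −1.492 and −0.984), so for these the share and DNBS cannot be told apart, because the lower quartile left room for both. The fall in calls to 68 was known before this test; it went with a median SE that rose from 0.331 to 0.428 for the higher and from 0.345 to 0.437 for the lower genes. An effect of DNBS on these transcripts remains open and untested beyond the comparison itself.

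Matrix remodelling genes rose with DNBS beside immune cell markers. With the mean of the neutrophil markers as a term the 12 members kept a median of 1.078 of their change (lower quartile 0.717, 12 of 12 with the same sign). The slope of this term comes from differences within groups. DNBS_GR159897 replicate 1, which stands apart, had the highest neutrophil mean of its group (3.557 against 2.138 and 1.762) and the lowest Timp1 (23.4 against 212 and 333 FPKM). No fit with the term left that library out, so the test cannot decide on RNA of neutrophils as the whole cause. With the macrophage markers as a term the members kept 0.685 (lower quartile 0.452), 10 of 12 with the same sign, and their median SE rose from 0.429 to 0.811. The list stayed past the fry threshold, unadjusted, with either term. RNA of macrophages and a change in glia cannot be told apart on these values, because the lower quartile left room for both. A response of glia to DNBS remains open and untested.

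Other splits of the same libraries were counted for each comparison. For DNBS averaged over both drug arms, 1 of 100 splits, the real one, gave 1226 genes or more, and the highest other gave 5. This share, under 0.05, argues against chance but does not exclude it, since the contrast was chosen after the results were seen. The splits also cannot separate DNBS from the annotated share, which differs between the same groups. For the interaction the real count was 0 (458 genes with an unadjusted p under 0.05 in limma), which each of the 100 splits reaches whatever the data, so the splits say nothing on chance there; the highest other gave 15. For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. DNBS_Vehicle against Saline_Vehicle gave 41 genes in the real split (1 split as large) and 2 in the highest other. DNBS_GR159897 against Saline_GR159897 gave 176 (1 split as large) and 1. Saline_GR159897 against Saline_Vehicle and DNBS_GR159897 against DNBS_Vehicle gave 0 with limma (217 and 1039 genes unadjusted), which all 10 splits reach by construction, so these 2 counts do not inform on chance either. The highest other splits gave 5 and 20, the latter with DNBS_Vehicle replicate 2 and DNBS_GR159897 replicate 3 exchanged.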

How the results depend on the processing

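The fits with all loci, scaled to the annotated total or with the annotated share as a term, and every test of DNBS averaged over both drug arms, were chosen after the results were seen. The causes of the changes below were not tested.

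Genes past the threshold, DNBS_Vehicle vs Saline_Vehicle (41) became 21 with a pseudocount of 0.1, 13 with no filter, 15 with a filter of 5 FPKM, 18 with the replicate block, 24 with a sex term, 514 with library weights, 110 with only the 2 groups, and 0 to 176 leaving out 1 library. DNBS_GR159897 vs Saline_GR159897 (176) became 42, 18, 31, 25, 2154 and 9 for a pseudocount of 0.1, no filter, block, sex, weights and 2 groups, 86 with upper-quartile scaling, 662 with all loci, 1 with the annotated share, and 4 to 604 leaving out 1 library. DNBS averaged over both drug arms (1226) became 442 with no filter, 800 with sex, 3009 with weights, 68 with the annotated share, 397 to 1655 leaving out 1. Counts of 0 became, for Saline_GR159897 vs Saline_Vehicle, 1 with a pseudocount of 0.1, upper-quartile scaling, quantile normalization, a filter of 5 FPKM or the annotated share, 5 with weights, and 0 to 3 leaving out 1. For DNBS_GR159897 vs DNBS_Vehicle they became 2 with a pseudocount of 0.1 or upper-quartile scaling, 3 with quantile normalization, 69 with weights, 79 with all loci, 5 scaled to the annotated total, and 0 to 6 leaving out 1. For the interaction they became 2 with a pseudocount of 0.1, 5 with weights, 1 scaled to the annotated total, and 0 to 2 leaving out 1. The unadjusted counts with limma were 217, 1039 and 458. Weights gave DNBS_GR159897 replicate 1 a weight of 0.18 and replicate 2 one of 4.22. The replicate numbers do not pair the samples (r of residuals −0.088 to 0.202).

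Apart from the apoptosis and p53 list, which had passed, the changes that reversed were of genes not past the threshold. With the annotated share as a term: S100b 0.037 averaged and 0.51 for DNBS_Vehicle vs Saline_Vehicle. Cdkn1a was at 0.60, Trp53 0.023 and Gfap 1.11 for DNBS_GR159897 vs Saline_GR159897, and Tac1 at 0.87 for DNBS_GR159897 vs DNBS_Vehicle. Scaled to the annotated total: Cdkn1a 0.005, Trp53 0.012 and Tacr2 0.25 for DNBS_GR159897 vs Saline_GR159897. Tacr2 was at 0.034 for Saline_GR159897 vs Saline_Vehicle, Tac1 0.45 for DNBS_GR159897 vs DNBS_Vehicle, Tacr1 0.083 for the interaction, and the apoptosis and p53 list (adjusted p = 0.907 averaged, 0.831 for DNBS_GR159897 vs Saline_GR159897). With weights: Tac1 0.16, Tacr2 0.36 and Tacr3 0.35 for DNBS_GR159897 vs DNBS_Vehicle. Tacr2 was at 0.19 for DNBS_GR159897 vs Saline_GR159897, and Tacr2 at 0.25 and Tacr3 −0.088 for Saline_GR159897 vs Saline_Vehicle. Tacr1 was at 0.041, Tacr2 0.11 and Tacr3 0.44 for the interaction. With quantile normalization and upper-quartile scaling: Tac1 0.27 and 0.10 for DNBS_GR159897 vs DNBS_Vehicle, Tacr2 0.17 and 0.12 for DNBS_GR159897 vs Saline_GR159897 and 0.020 and 0.007 for Saline_GR159897 vs Saline_Vehicle. With a sex term: Tacr2 0.16 for DNBS_GR159897 vs Saline_GR159897.

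Leaving out 1 library, these changed sign over the ranges given. DNBS_Vehicle vs Saline_Vehicle: Sox10 −1.77 to 0.77, Tacr2 −0.17 to 1.04. Saline_GR159897 vs Saline_Vehicle: Sox10 −0.091 to 1.87, Rpl22 −0.85 to 0.01, Tacr2 −0.37 to 0.33, Tacr3 −0.28 to 0.22. DNBS_GR159897 vs DNBS_Vehicle: Tac1 −0.98 to 0.48, Tacr1 −0.062 to 0.58, Tacr2 −1.08 to 0.13. DNBS_GR159897 vs Saline_GR159897: Tacr1 −0.10 to 0.73, Tacr2 −0.37 to 0.49. Interaction: Tac1 −0.57 to 0.89, Tacr1 −0.61 to 0.22, Tacr2 −1.04 to 0.17. Averaged: Tac2 −0.020 to 0.61, Tacr2 −0.090 to 0.52.

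The annotated share as a term ended most calls of named genes, 83 in a single fit. Of the same calls 58 were lost with no filter, 36 with a sex term, 33 with the block and 32 with a pseudocount of 0.1. Scaling to the annotated total lost 22, upper-quartile scaling 15, a filter of 5 FPKM 13 and quantile normalization 11. Fits of only the 2 groups, run for pairwise comparisons alone, lost 21. Leaving out 1 library lost 398, a sum over 12 fits for each call. Of the list calls, 49 were lost over all leave-one-out fits, 7 with the annotated share, 3 with sex and 6 with the block. The annotated total lost 4, upper-quartile scaling 2 and quantile normalization 3. With camera 18 were lost with an estimated correlation and 5 with the preset one. With the annotated total 2 more were lost with their direction reversed. Count-based tools and recovered reads were not run, since the table holds no counts; upper-quartile scaling stands in for TMM. The unknown depth limits what can be said of genes at a few FPKM, Tacr2 among them.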

Other observations

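The tests of the averaged DNBS contrast and of DNBS_GR159897 replicate 1 in this part were chosen after the results were seen.

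Some members of lists that did not pass differed in the DNBS change averaged over both drug arms. Hk2, the hexokinase that starts glycolysis, rose by 2.52 (adjusted p = 0.0122) and Hif1a, the hypoxia-inducible transcription factor, by 1.21 (adjusted p = 0.0214), while the hypoxia and glycolysis list as a whole had a median of 0.14 (adjusted p = 0.697). Aldoa at −1.63, Bnip3 at −1.32 and Slc2a1 at −0.75 of that list fell when adjusted over the list alone (0.0202, 0.0202 and 0.0314) and did not pass over all genes. Cybb, the catalytic subunit of the phagocyte oxidase, rose by 1.19 (adjusted p = 0.0101), heme oxygenase Hmox1 by 1.00 (adjusted p = 0.0454) and the thioredoxin reductase Txnrd1 by 0.92 (adjusted p = 0.0445), in an oxidative stress list with an adjusted p of 0.129. Lif, a cytokine of nerve injury, rose by 2.09 (adjusted p = 0.0136), in a neurotrophic list with an adjusted p of 0.704; it is also a member of the cytokine and chemokine list, which passed. Gfra1 of the neurotrophic list was at −2.26 (0.0425 adjusted over the list alone, not past over all genes). The myelin protein Mbp fell by −2.01 (adjusted p = 0.00463) in a list with an adjusted p of 0.253. Of these, Hk2, Cybb, Lif and Mbp passed in all 12 fits that left out 1 library. Hif1a did not pass without Saline_Vehicle replicates 1 and 3 or Saline_GR159897 replicate 3 (adjusted p up to 0.0672). Hmox1 passed only without DNBS_GR159897 replicates 1 or 2 (adjusted p of 0.0539 to 0.111 in the other fits) and Txnrd1 only without DNBS_Vehicle replicate 3 or DNBS_GR159897 replicates 1 or 3 (0.0639 to 0.115). Of the 4 fully held genes only Lif passed with the annotated share as a term.

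Neuronal genes were measured beside the glial ones. Calb2, the calcium-binding protein calretinin of enteric neurons, fell by −2.19 (adjusted p = 0.0214), and did not pass without Saline_Vehicle replicate 3 or Saline_GR159897 replicates 1 and 3 (adjusted p up to 0.0611). Gal, the neuropeptide galanin, lay between 116 and 262 FPKM in the 6 saline libraries and at 918, 690 and 1669 FPKM in DNBS_Vehicle. In DNBS_GR159897 it was at 39.2, 766 and 1074 FPKM, and the change of 1.62 did not pass (adjusted p = 0.158). The neuron list had a median of −0.45 (adjusted p = 0.704). The immediate early gene Nr4a1 fell by −1.99 (adjusted p = 0.0202). Nr4a1 did not pass without Saline_Vehicle replicates 1 and 3 (adjusted p up to 0.0579), and Btg2 rose by 1.18 (adjusted p = 0.0244). Btg2 did not pass without Saline_Vehicle replicates 1 and 3, DNBS_Vehicle replicate 1 or Saline_GR159897 replicates 1 and 3 (adjusted p up to 0.0737).

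In the same averaged contrast the other lists had adjusted p of 0.0666 for the cell cycle, 0.123 for immediate early genes, 0.137 for the unfolded protein response, 0.166 for endothelium, 0.574 for cholesterol synthesis, 0.618 for mesothelium, 0.704 for complement, the tachykinin system and interstitial cells of Cajal, and 0.792 for fibroblasts. The tachykinin median was 0.32 while its test pointed down, and the fibroblast median −0.27 while its test pointed up.

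DNBS_GR159897 replicate 1 differed from the other libraries of its group in more than epithelial and smooth muscle markers. Neutrophil markers lay higher by a median of 1.717 and cell cycle genes by 1.777 (9 of 12 above both other libraries), and Mki67 was at 41.7 FPKM. Neuron markers lay lower by a median of −2.093 (17 of 17 below both).

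Some genes had uneven levels within groups or no values, and why was not tested. Sox10 was at 1.3, 4.63 and 6.79 FPKM in DNBS_GR159897, while S100b in replicates 2 and 3 of that group was at 94.0 and 135 FPKM. The same was seen outside that group, with Sox10 at 15.4 and S100b at 202 FPKM in Saline_Vehicle replicate 2, and at 9.04 and 108 FPKM in DNBS_Vehicle replicate 1. The mitochondrial gene mt-Nd6 was at 160, 2.36 and 42.7 FPKM in Saline_Vehicle and at 0.17 FPKM or less in the other 9 libraries. Gfap had no values in Saline_Vehicle and lay between 0.90 and 323 FPKM elsewhere. Cela1, a pancreatic elastase gene, was the single digestive enzyme gene past the filter.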
